A study of Mus musculus with 4 samples.

How the data were processed

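RNA from 4 mouse placenta samples at embryonic day 14.5 was measured on Affymetrix expression arrays, 1 array per sample, with 2 arrays labelled wild type and 2 labelled Syde1 knockout. Per the labels' protocols, the uterine wall, the fetus and the yolk sac were taken off each conceptus with forceps and scissors to leave the individual placenta, and total RNA was extracted with TRIzol and purified on columns. Litter, strain, sex, the targeted exon and whether RNA of several placentas was pooled are not given in the sources used here.

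The deposited table holds 1 value per probe set and array. Per the submitters' processing notes, the authors made these values with RMA in Affymetrix Expression Console 1.2. RMA subtracts background, quantile-normalizes the arrays and summarizes the probes of a set by median polish. The options used are not given in the sources used here. The deposited values are on the log2 scale, which was read from their range (1.17 to 14.41), and are rounded to 2 decimals. The medians of the 4 arrays lay between 5.95 and 5.98, so no further normalization was applied. Arrays have no read depth, and their number, 2 per group, limits the precision.

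The table has 45101 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which left 45037. Genes were named through the platform annotation. Of the probe sets tested, 34945 had 1 gene symbol, 932 had several and 9160 had none listed, and only those with 1 symbol were named. The Entrez identifiers of 34741 of them were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. That table was used for names and for which genes neighbour each other, and its coordinates are not reported. No intensity filter was applied.

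The knockout-labelled arrays were compared with the wild-type arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, genotype as the single term), two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets. The fit has 2 residual degrees of freedom, and the empirical Bayes prior adds 3.50. Adjusted p under 0.05 was called. Differences are knockout-labelled minus wild type on the log2 scale, given with the standard error (SE) of the fit. A probe set was also described as separated where both arrays of a group lay on the same side of both arrays of the other, which chance gives for 33.3% of probe sets. Separated probe sets with at least a 2-fold difference were counted without a test.

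Gene lists were fixed before the data were examined: 36 of cell type markers, gene families, pathways and technical signs, and 1 rule for the genes within 5 Mb of Syde1. Of the 689 symbols listed by name, 618 were measured. Each gene entered by its brightest probe set. The 36 lists with at least 5 measured members were tested by limma's camera with the preset inter-gene correlation of 0.01 against all other genes, two-sided, with Benjamini-Hochberg adjustment over the 36. The X-inactivation transcripts, with 2 members, were given as values.

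Genes were named by a rule fixed before the data were examined. It takes Syde1, its flanking list, Xist and the Y-linked genes. It takes the 12 largest differences in each direction among separated genes with adjusted p under 0.05, leaving out predicted genes, small RNAs and chemosensory receptors. Where fewer passed, the places were filled by size from separated genes with an unadjusted p under 0.01, which did not pass. From each list it takes the members that passed, the 4 largest where more than 4 did, or, where none passed, 2 members with the smallest p, as values. Any gene named outside this rule is said to be chosen after its values were seen.

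The alternatives fixed before the data were examined were an intensity trend and a robust prior in eBayes, a replicate block, a second quantile normalization, median centring, probe sets at or above the median brightness, probe sets with 1 symbol, array weights, the mean of a gene's probe sets, camera with an estimated correlation, fry, looser thresholds, and leaving out each array in turn. Another 2 were added after seeing the data: testing 1 probe set per gene, and leaving out probe sets of 0 variance. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the fit, which it does not with the preset one. It can then hardly call a list over 36. The closing section gives the effect of the alternatives. Tests of gene positions and matched random lists were run in Python 3.11.15 with 10000 draws each.

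The limma fit was tested on simulated data of the same size, 45037 probe sets of which 200 were changed. It recovered 0% of those with a log2 difference of 1, 90.0% at 2 and 100% at both 4 and 8, with 5 false among 150 calls. These rates do not carry over to the data. The many planted changes ease the Benjamini-Hochberg cutoff, and the simulated SDs were drawn from the prior. In the data Apoa1 differed by 4.87 and Ttr by 4.53, and neither was called. In simulated list tests over 18193 genes, 50 of 50 lists of 15 genes shifted by 0.3 were called, and 1 of 50 unshifted lists. The simulated genes had independent errors. Estimated correlations in the measured lists reached 0.377 for yolk sac endoderm and 0.943 for cell cycle genes. The simulation therefore does not show how often camera calls unshifted lists in these data.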

Results

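Gene expression was measured on 4 Affymetrix arrays, 1 per mouse placenta sample at E14.5, counted in embryonic days, from 2 samples labelled wild type and 2 labelled Syde1 knockout. Syde1 encodes a Rho GTPase-activating protein, and the series title ties it to fetal growth restriction and to the movement and invasiveness of cells of the placenta. The deposited values are RMA log2 expression. Correlation across probe sets was 0.992 between the wild-type arrays and 0.992 between the knockout-labelled arrays. It was 0.994 between the second array of each group, the highest of the 6 pairs, and 0.989 to 0.991 in the other pairs of different groups. The titles number the samples of each group separately. The p-values rest on the spread between these samples only, and more on a prior pooled over all probe sets (3.50 degrees of freedom) than on each probe set's own spread (2). Group values below are means ± SD with n = 2 arrays per group, and differences are knockout-labelled minus wild type in log2 units.

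The targeted gene was not lower in the knockout-labelled arrays. The Syde1 probe set (1431798_a_at) read 8.93 and 8.98 in the wild-type arrays and 9.05 and 9.10 in the arrays labelled knockout. The difference was 0.12 (SE 0.13, 95% interval -0.19 to 0.43) with a limma adjusted p of 0.998. The part of the gene that was deleted is not given in the sources used here, so these probes may lie outside it and then check nothing about the labels.

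The first comparison asked which transcripts differed between the 2 genotypes. Of 45037 probe sets, 5 rose in the knockout-labelled arrays and 0 fell at a limma adjusted p under 0.05. Rnase2a, which encodes an eosinophil-associated ribonuclease, rose from 4.12 ± 0.24 to 12.81 ± 0.17 (adjusted p = 0.00077). Ang2, the array's symbol for a ribonuclease of the angiogenin family and not for angiopoietin 2, rose from 3.02 ± 0.22 to 9.26 ± 0.45 (adjusted p = 0.014). The wild-type readings of both lay below the first quartile of their arrays (4.44 to 4.53) and are not shown to be above background, so no size is given for the rise. Spink1, a secreted trypsin inhibitor, rose 13.4-fold from 5.07 ± 0.28 to 8.81 ± 0.08, and Alb, the plasma protein albumin, rose 11.6-fold from 5.66 ± 0.17 to 9.20 ± 0.16, both with an adjusted p of 0.018. The remaining probe set, 1458629_at, has no gene listed and rose by 2.31 (adjusted p = 0.033).

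Genes filling the places for the largest positive differences did not pass over all probe sets. Most of them encode secreted plasma proteins. Apoa1, the main protein of high-density lipoprotein, had means of 6.80 ± 0.62 and 11.67 ± 0.30 (adjusted p = 0.0503). Spp2, a secreted phosphoprotein, differed by 3.91 (SE 0.26) with the same adjusted p, and by 0.01 on a second probe set. Differences of the transport proteins Ttr and Apob were 4.53 (SE 0.51) and 4.29 (SE 0.52). A second probe set of Apob differed by 0.32. The fibrinogen chain Fgg differed by 3.91 (SE 0.37) and the antitrypsin gene Serpina1b by 4.46 (SE 0.41). Fga, another fibrinogen chain, and Serpina1c, another antitrypsin gene, had wild-type means below the first quartile of the arrays too, and knockout-labelled means of 7.93 ± 0.78 and 8.18 ± 0.81.

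No gene fell, and the places for the largest negative differences were filled by genes that did not pass. Within the limit set for filling, an unadjusted p under 0.01, the Y-linked translation factor gene Eif2s3y had the largest, at -2.90 (SE 0.72). A second probe set of Eif2s3y, below the first quartile of the arrays in both groups, differed by -0.04. Kdm5d, another Y-linked gene, lay lower, at -3.71 (SE 0.98), and missed the limit for filling (unadjusted p = 0.011). Its other probe sets differed by 0.165 and -0.56. In the first knockout-labelled array Eif2s3y (3.86) and Kdm5d (1.86) read below the first quartile. These readings are not shown to be above background, so both sizes are uncertain. The next were Ppp1r3e, a glycogen-targeting subunit of protein phosphatase 1, at -0.95 (SE 0.19), the lipid kinase gene Pik3cd at -0.94 (SE 0.23) and the small GTPase gene Gem at -0.92 (SE 0.13). Other probe sets of Pik3cd differed by -0.53 to 0.02. Prss21, Npn2 and Slc22a17 lay between -0.72 and -0.61. Atp1b4, Itln1, Ptafr, Zic4 and Frmpd3 filled the remaining places but lay below the first quartile of the arrays in both groups, so no size is given. A second probe set of Npn2 differed by 0.15.

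Without a test, 166 probe sets were separated by at least 2-fold, 150 of them higher and 16 lower in the knockout-labelled arrays. The higher ones include the brightest probe sets of 15 yolk sac endoderm genes, and the lower ones those of 3 Y-linked genes. Both lists are described below. Over all probe sets 30.3% were separated, below the 33.3% that chance gives. The number at an unadjusted p under 0.05 was 2122, below the 2251.9 that chance gives. The count of separated 2-fold probe sets was 301 without the first wild-type array (241 higher, 60 lower), 271 without the second (185 higher, 86 lower), 160 without the first knockout-labelled array (129 higher, 31 lower) and 409 without the second (350 higher, 59 lower), where a lone array is separated from a pair more easily. Leaving out any one of the 4 arrays ended the limma calls, with 0 probe sets called and 1191 to 2075 at an unadjusted p under 0.05. Other settings of the fit with all arrays called from 1 to 29 probe sets, each of them higher.

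Genes of the yolk sac endoderm, the epithelium that secretes plasma proteins and takes up maternal protein, rose as a group. Of 16 measured members, 15 were separated and at least 2-fold higher, against 33.3% separated by chance. The exception was the vitamin E transfer protein gene Ttpa, at 0.04 (SE 0.13); this gene, Afp, Cubn and Amn were chosen after their values were seen. Alb and Spink1 passed over all probe sets, and 15 members passed when adjusted over the list alone. The list's median difference was 3.39 (camera adjusted p = 3.5e-48). With an estimated correlation the call was lost (adjusted p = 0.906 with an estimated correlation, range over alternatives 4.8e-53 to 0.906). Afp, the fetal counterpart of albumin, was bright in both groups at 10.25 ± 0.40 and 13.03 ± 0.23. The partners of the protein uptake receptor, Cubn and Amn, differed by 3.16 (SE 0.43) and 2.72 (SE 0.37). The protocol says that the yolk sac was removed from each placenta. Members also differed between arrays of 1 group, with 13 of 16 higher in the first knockout-labelled array than in the second and a median gap of 0.63.

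**Figure D1:**
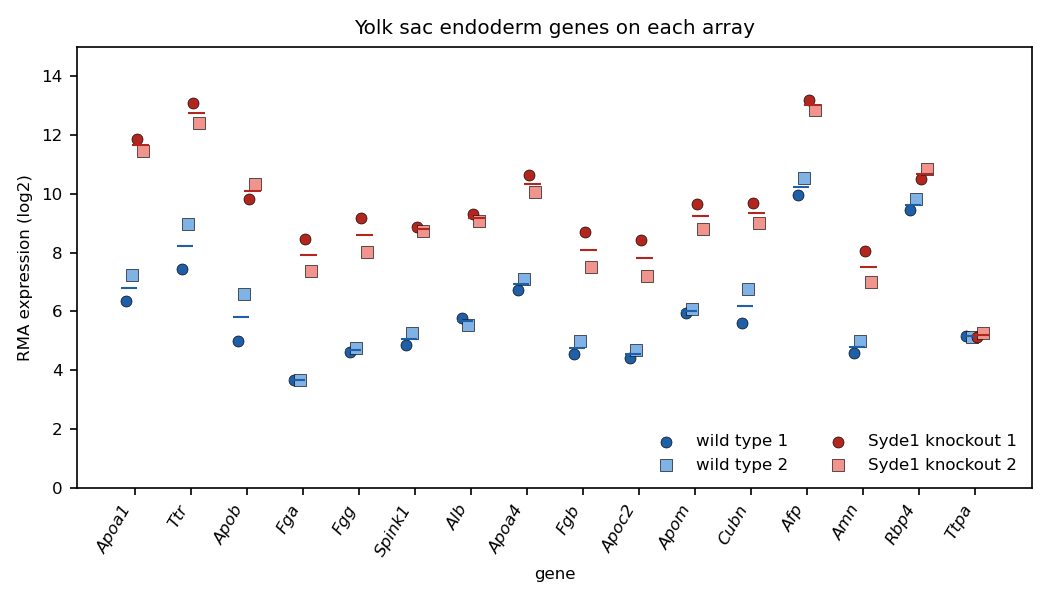
RMA expression (log2) of the 16 measured yolk sac endoderm genes on each array, ordered by difference, with bars at the group means (n = 2 each). Both knockout-labelled arrays lie above both wild-type arrays for 15 genes, and Ttpa lies near 5.2 on all 4 arrays.

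Y-linked genes, which are transcribed in males, fell as a group (5 measured, median difference -1.85, camera adjusted p = 1.6e-06). The call was lost with an estimated correlation (adjusted p = 0.907 with an estimated correlation, range over alternatives 3.0e-08 to 0.907). All 5 members were separated and lower, 4 passed adjusted over the list alone, and 0 passed over all probe sets. The 2 knockout-labelled arrays differed. Kdm5d, a histone demethylase, read 7.17 and 7.20 in the wild-type arrays, 1.86 in the first knockout-labelled array and 5.10 in the second. Eif2s3y read 7.75 and 8.08, then 3.86 and 6.18. Uty, another histone demethylase gene, read 6.07 and 6.49, then 3.58 and 5.29. The brightest probe sets of Zfy2 and Usp9y differed by -0.41 (SE 0.13) and -0.17 (SE 0.15). Xist, the RNA that coats the inactive X chromosome of female cells, lay at 11.92 ± 0.02 in wild type and 12.55 ± 0.02 in the knockout-labelled arrays on its brightest probe set. Its other probe sets differed by 1.54 and 1.78, and its antisense partner Tsix by 0.11 (SE 0.15). Xist passed adjusted over its list of 2 alone and not over all probe sets. These signs of sex moved with the genotype labels.

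**Figure D2:**
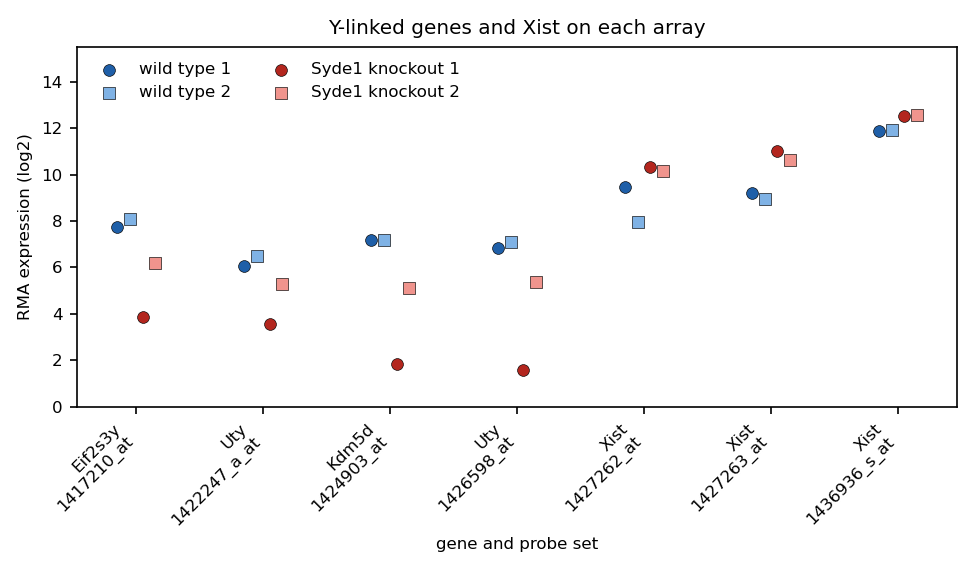
RMA expression (log2) on each array of the 4 probe sets of Y-linked genes with a wild-type mean of at least 5 and of the 3 probe sets of Xist. On each Y-linked probe set the wild-type arrays are highest, the first knockout-labelled array is lowest and the second lies between them.

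The placental cell types showed no called shift in the main test. Spongiotrophoblast genes, from the endocrine layer of the junctional zone, had a median difference of -0.09 over 23 members (adjusted p = 0.169), with Prl7a1 at 0.35 (SE 0.17) and Prl2b1 at -0.19 (SE 0.13). Glycogen trophoblast genes had a median of -0.10 over 11 members (adjusted p = 0.090), with Aldh1a3 at -0.63 (SE 0.28) and Gbe1, the glycogen branching enzyme, at -0.31 (SE 0.16). Trophoblast giant cell genes had a median of -0.06 over 11 members (adjusted p = 0.865), with the transcription factor gene Hand1 at 0.52 (SE 0.14) and Lifr at -0.38 (SE 0.16). Labyrinth syncytiotrophoblast genes had a median of 0.00 over 18 members (adjusted p = 0.756), with Cebpa at 0.39 (SE 0.14) and the lactate transporter gene Slc16a3 at 0.37 (SE 0.16). None of these 4 lists had a member that passed. Other probe sets of Prl7a1 differed by 1.09 and 1.135, and another of Aldh1a3 by -1.125, each separated and none passing. Spongiotrophoblast genes were called lower without the first wild-type array (adjusted p = 0.023) and without the second knockout-labelled array (0.019), in a range over alternatives of 0.019 to 0.993. Glycogen trophoblast genes were called lower among probe sets at or above the median brightness (0.047, range 0.047 to 0.907).

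Among placental gene families, the prolactin family (17 members, median -0.09, adjusted p = 0.561) and the placental cathepsins (11 members, median -0.08, adjusted p = 0.152) were not called. Ctsm, a trophoblast cathepsin, differed by -0.25 (SE 0.27) and Ctsll3 by -0.38 (SE 0.20). The pregnancy-specific glycoproteins with Ceacam genes fell slightly as a list (12 members, median -0.18, adjusted p = 0.026), with 0 members passing and 1 separated. The call was lost with an estimated correlation (adjusted p = 0.947 with an estimated correlation), after a second quantile normalization (0.094) and without the second wild-type array (0.535). It turned upward without the first knockout-labelled array (adjusted p = 0.690, range over alternatives 4.7e-05 to 0.993). Psg21 differed by -0.20 (SE 0.15) and Ceacam14 by -0.19 (SE 0.14).

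Immune cell genes shifted little. Macrophage genes rose as a list (14 members, 7 separated and higher, median 0.16, adjusted p = 0.0063). The call was lost with an estimated correlation (adjusted p = 0.907 with an estimated correlation, range over alternatives 8.9e-05 to 0.993). The complement gene C1qb differed by 0.43 (SE 0.19) and the Fc receptor gene Fcgr1 by 0.29 (SE 0.13). Neutrophil genes rose as a list (12 members, 5 separated and higher, median 0.18, adjusted p = 0.035). Their call was lost with an estimated correlation as well (adjusted p = 0.907 with an estimated correlation, range over alternatives 0.0078 to 0.907). Their largest difference was that of Lcn2, an iron-binding protein also made by epithelia, at 1.34 (SE 0.23), which passed adjusted over the list alone. Mpo, the granule peroxidase, differed by 0.39 (SE 0.16). The macrophage and neutrophil calls were also lost without the second wild-type array, at 0.147 and 0.488, and without the second knockout-labelled array, at 0.919 and 0.263. T and B lymphocyte genes (8 members, median -0.07, adjusted p = 0.147) were not called, with the T cell receptor chains Cd3g at -0.46 (SE 0.22) and Cd3d at -0.23 (SE 0.18).

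The uterine and blood lineages were not called in the main test. Uterine natural killer genes had a median of -0.26 over 16 members (adjusted p = 0.090) with 0 separated, and the granzymes Gzmd and Gzme differed by -0.41 (SE 0.34) and -0.49 (SE 0.51). Within wild type their median differed by -1.18 between the second and the first array. The list lay higher without the first wild-type array (adjusted p = 0.0018) and lower without the second (adjusted p = 1.2e-09), without the first knockout-labelled array (0.034) and at or above the median brightness (0.021), in a range over alternatives of 1.2e-09 to 0.993. Decidual stroma genes had a median of 0.04 over 15 members (adjusted p = 0.756), with Sfrp1 at 0.59 (SE 0.25) and Hoxd10 at 0.25 (SE 0.25). Genes of uterine gland and smooth muscle had a median of 0.14 over 9 members (adjusted p = 0.090), with Myocd at 0.65 (SE 0.16) and Actg2 at 0.50 (SE 0.24). Erythroid genes had a median of 0.21 over 17 members (adjusted p = 0.169), with the globin gene Hbb-b2 at 0.53 (SE 0.14) and the heme synthesis gene Alas2 at 0.39 (SE 0.15). Platelet and megakaryocyte genes had a median of 0.21 over 8 members (adjusted p = 0.561), with Gp9 at 0.25 (SE 0.16) and Gp6 at -0.18 (SE 0.15). Decidual stroma genes were called higher without the first wild-type array (adjusted p = 0.00041) and lower without the second (0.0065), in a range over alternatives of 0.00041 to 0.993. Without the second knockout-labelled array erythroid genes (0.0016, range 0.0016 to 0.993) and platelet genes (0.0070, range 0.0070 to 0.993) were called higher. Uterine gland and smooth muscle genes were called higher without the first (0.034, range 0.034 to 0.993).

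Vessel and stroma genes were not called in the main test either. Endothelial genes had a median of 0.05 over 18 members (adjusted p = 0.661), with Vwf at 0.35 (SE 0.13) and Pecam1 at -0.28 (SE 0.17). Angiogenic factors had a median of -0.01 over 23 members (adjusted p = 0.756), with the placental growth factor gene Pgf at 0.31 (SE 0.13) and Thbs1 at -0.30 (SE 0.15). Mesenchyme and pericyte genes had a median of -0.03 over 15 members while their mean was 0.06 (adjusted p = 0.603). The collagen genes Col1a2 and Col1a1 differed by 0.73 (SE 0.16) and 0.76 (SE 0.34), and another probe set of Col1a1 by 1.065. Endothelial genes were called higher without the second wild-type array (adjusted p = 0.019, range over alternatives 0.019 to 0.993).

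Lists on cell movement and invasion, the theme of the series title, were not called in the main test. Matrix proteases and inhibitors had a median of 0.05 over 27 members (adjusted p = 0.865), and the collagenase gene Mmp1a had means of 9.66 ± 0.16 and 8.69 ± 0.60. Mmp19 differed by -0.38 (SE 0.14). Extracellular matrix genes had a median of 0.04 over 32 members (adjusted p = 0.169), with Col6a1 at 0.70 (SE 0.15). Integrin and adhesion genes had a median of 0.08 over 26 members (adjusted p = 0.063), with the fibronectin receptor subunit Itga5 at 0.73 (SE 0.17) and the focal adhesion gene Zyx at 0.45 (SE 0.14). Actomyosin genes had a median of 0.05 over 29 members (adjusted p = 0.561), with Tpm2 at 0.24 (SE 0.13) and Msn at -0.22 (SE 0.13). Rho GTPases with their regulators, the class Syde1 belongs to, had a median of 0.00 over 39 members (adjusted p = 0.756), with Arhgdib at 0.47 (SE 0.15) and Arhgef12 at -0.32 (SE 0.16). Integrin and adhesion genes were called higher without the second wild-type array (adjusted p = 0.019) and without the first knockout-labelled array (0.020), in a range over alternatives of 0.019 to 0.993. Extracellular matrix genes were called higher without the same arrays (0.047 and 0.034, range 0.034 to 0.993).

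Lists on growth, nutrition and metabolism were not called in the main test. Imprinted genes had a median of 0.01 over 31 members although camera put their direction downward (adjusted p = 0.884), with Nnat at 1.23 (SE 0.37) and Igf2r at 0.30 (SE 0.14). Nutrient transporters had a median of -0.08 and a mean of 0.07 over 24 members (adjusted p = 0.756). The fatty acid transporter gene Slc27a2 had means of 4.42 ± 0.74 and 7.05 ± 0.74 and passed adjusted over the list alone, and Lpl differed by 0.57 (SE 0.15). Steroid hormone synthesis had a median of 0.12 over 12 members (adjusted p = 0.169). Hsd3b1 differed by 1.14 (SE 0.46) and Star by 0.33 (SE 0.16), and another probe set of Star by 1.025. Hypoxia and glycolysis had a median of -0.02 over 23 members (adjusted p = 0.561), with Hk1 at 0.25 (SE 0.14) and P4ha2 at -0.27 (SE 0.17). Mitochondrial respiration had a median of 0.08 over 28 members (adjusted p = 0.090), with Sdhc at 0.35 (SE 0.13) and Cox4i1 at 0.24 (SE 0.13). Ribosomal proteins had a median of 0.03 over 22 members (adjusted p = 0.892), with Rps2 at 0.17 (SE 0.14) and Rpl19 at 0.14 (SE 0.13). Mitochondrial genes lay a median of 0.30 higher in the first knockout-labelled array than in the second. They were called higher without the second (adjusted p = 1.4e-05) and without the first wild-type array (0.033), in a range over alternatives of 1.4e-05 to 0.993. Steroid synthesis genes were called higher without the first wild-type array (0.046, range 0.046 to 0.907), and ribosomal proteins lower without the first knockout-labelled array (0.034, range 0.034 to 0.993).

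Cell cycle genes differed more within each group than between the groups. In wild type the second array differed from the first by a median of -0.51. The knockout-labelled mean lay above wild type for 28 of 29 members (median 0.19, adjusted p = 0.234), but 0 were separated, and the first knockout-labelled array lay above the second by a median of 1.40. Mcm6 differed by 0.25 (SE 0.28) and Aurka by 0.46 (SE 0.56). The list lay lower without the first knockout-labelled array (adjusted p = 3.4e-11) and higher without the second (adjusted p = 1.9e-14) and without the first wild-type array (0.010), in a range over alternatives of 1.9e-14 to 0.993.

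Of the stress lists, 2 fell and 1 rose, all by small amounts. Interferon response genes fell (21 members, 4 separated and lower, median -0.12, adjusted p = 0.0063). The call was lost with an estimated correlation (adjusted p = 0.931 with an estimated correlation, range over alternatives 5.0e-10 to 0.993). The chemokine gene Cxcl10 differed by -0.45 (SE 0.14) and Oasl2 by -0.31 (SE 0.13). Genes of the unfolded protein and integrated stress response fell (20 members, 5 separated and lower, median -0.13, adjusted p = 0.0087). Their call was lost with an estimated correlation too (adjusted p = 0.931 with an estimated correlation, range over alternatives 0.00043 to 0.993). Trib3 differed by -0.37 (SE 0.15) and the chaperone gene Hsp90b1 by -0.31 (SE 0.13). Immediate early genes, which cells can switch on within minutes, rose (24 members, 8 separated and higher, median 0.15, adjusted p = 0.0099). This call was lost with an estimated correlation (adjusted p = 0.907 with an estimated correlation, range over alternatives 0.0050 to 0.907). Hspa1a differed by 0.77 (SE 0.26) and Jund by 0.29 (SE 0.13). Each of the 3 calls was also lost without some arrays: the interferon list without the first array of either group, at 0.228 in the opposite direction and at 0.124, the unfolded protein list without the second wild-type array (0.338) or the first knockout-labelled array (0.570), and the immediate early list without the second array of either group (0.114 and 0.143). Exogenous control RNAs, added in fixed amounts during labelling and hybridization, shifted between the groups by a median of 0.24, more in size than the median of each of these 3 lists.

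Genes within 5 Mb of Syde1 were read as a separate list. Of 211 measured, 49 were separated and higher and 17 separated and lower, against 33.3% separated by chance in either direction. Their median difference was 0.05 (adjusted p = 0.090), and 0 passed over all probe sets or adjusted over the list alone. The list was called higher without the first wild-type array (adjusted p = 0.033) and without the second knockout-labelled array (0.044), in a range over alternatives of 0.033 to 0.907. Col6a1 belongs to this list too, and Trpm2 differed by -0.49 (SE 0.13).

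Of 36 lists tested, 8 were called by camera with the preset correlation, 4 higher and 4 lower, and 28 were not (adjusted p from 0.063 to 0.892). With an estimated correlation camera called 0, with 1 list at an unadjusted p under 0.05, and fry called 0, with 1 list. The estimate was 0.015 for immediate early genes and -0.027 for neutrophil genes, near or below the preset 0.01. Their unadjusted camera p still went from 0.0017 to 0.096 and from 0.0077 to 0.107. A higher correlation therefore does not account for the loss of these calls. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, which by itself raises p. Even yolk sac endoderm, with a median of 3.39, reached an unadjusted camera p of only 0.025 in that setting. The lost calls there reflect low power and say little about any 1 list. Yolk sac endoderm and Y-linked genes were the lists that kept their call whichever array was left out.

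**Figure D3:**
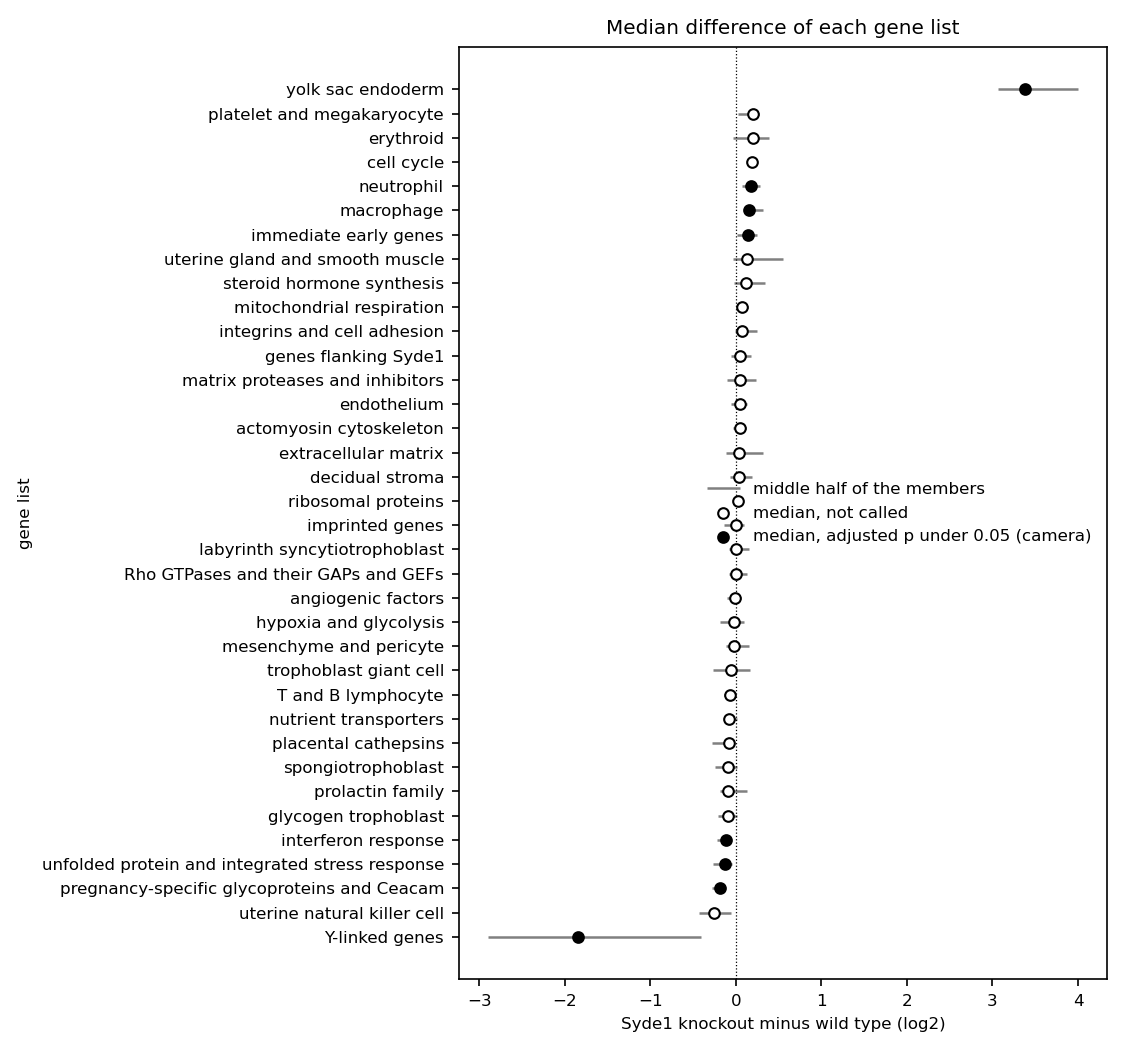
Median difference (log2, knockout-labelled minus wild type) of the 36 gene lists tested, with lines over the middle 50 percent of members and filled points for lists called by camera. Yolk sac endoderm lies at 3.39, Y-linked genes at -1.85, and each other list within 0.26 of 0.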

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

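All tests of explanations in this part were chosen after the results were seen. The Affymetrix control probe sets, which take part in no comparison, differed between the groups. Of 45 probe sets for exogenous controls, bacterial and phage RNAs added at fixed amounts during labelling and hybridization, 36 had both knockout-labelled arrays above both wild-type arrays and 4 had both below, against 33.3% separated in either direction by chance. Control probe sets of 1 RNA are not independent, and 1 factor per array can move the probe sets of many RNAs together. Chance would separate such a factor in 33.3% of cases, so these counts alone do not show a difference between the groups. The largest difference was 0.925, on a probe set for the phe spike, and the median was 0.24. That phe probe set read 3.74 and 4.03 in the wild-type arrays, below their first quartiles. The gap between the 3' and 5' probe sets of Gapdh was 0.06 and -0.01 in the wild-type arrays and 0.15 and 0.16 in the knockout-labelled arrays. For actin it was 0.75 and 0.76, then 0.83 and 0.88. Among mouse controls, Gapdh and actin probe sets differed by -0.05 to 0.08. Those of the transferrin receptor differed by -0.69 at the 5' end, -0.365 in the middle and -0.24 at the 3' end. Those of 18S RNA ran the other way, from -0.27 at the 5' end to -0.355 at the 3' end. The groups thus differed in labelling, hybridization or spike amounts, which these controls do not tell apart, and RNA integrity was not tested. Lists that shifted by 0.1 to 0.3 lie within the size of the exogenous shifts, which does not show that the same cause moved them.

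Yolk sac endoderm genes were higher in the knockout-labelled arrays by a median of 3.39. An array processing difference is argued against by size, since the largest exogenous control shift was 0.925. Yolk sac tissue left on some placentas may account for the rise, although the protocol says it was removed: within both groups the list moved together by more than any of 10000 lists matched on expression (percentile 100 in the group with the smaller one). That test separates poorly, because 19 of 36 lists lay outside the central 95% in both groups. None of the 16 genes is held by another list, and how many of them placenta itself expresses was not tested. No list of liver genes was fixed, so the rise is not shown to be specific to yolk sac. An effect of genotype and one of sex stay open and untested, since both go with the groups.

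Y-linked genes were lower in the knockout-labelled arrays, and intermediate in the second. A male placenta diluted by maternal tissue is argued against. In the second knockout-labelled array 63 trophoblast genes lay a median of 0.03 above wild type, where the Y-linked drop was -1.67. The 95% bootstrap interval of -0.05 to 0.12 resamples genes of 1 array as if independent, so it does not measure the spread between placentas. Spongiotrophoblast genes alone differed by a median of 0.23 between the wild-type arrays. A mixture of male and female tissue in the second knockout-labelled array cannot be told apart from other causes. On a linear scale that sets the wild-type mean to 100% and the first knockout-labelled array to 0%, the second lay at a median of 28.3% on the Y-linked probe sets (21.6% to 41.3%) and of 18.2% on the Xist probe sets (-6.05% to 30.4%). That is not a male share, since the wild-type arrays held Xist as well. Pooling is not given in the sources used here, and the sex of the samples is confounded with genotype.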

How the results depend on the processing

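The count of called probe sets was 5, and another 8 tied at an adjusted p of 0.0503, so small changes can raise it. It was 13 with an intensity trend, 29 with a robust prior, 18 after a second quantile normalization, 21 after median centring, 16 in probe sets at or above the median brightness, 14 with 1 symbol, 13 with array weights, 21 at an adjusted p under 0.1, and 28 without the 56 probe sets of 0 variance (chosen after seeing the data). That last step raised the prior degrees of freedom from 3.50 to 4.21, so replicates made equal by rounding to 2 decimals lowered the count. It was 0 to 0 with an array left out, when 1 residual degree of freedom remained, 972 to 997 probe sets had 0 variance and the lone array was assumed to vary like the other group. Testing 1 probe set per gene gave 6. With a replicate block it was 1, Rnase2a; the numbers are shared by 2 pairs with a correlation of deviations of 0.265, which does not show that they pair the samples. The other splits of the 4 arrays, which are too few for a test, called 0 and 0, with 3898 and 1118 at an unadjusted p under 0.05. The split that sets both first arrays against both second arrays also separated 256 probe sets by 2-fold, against 166 for genotype, which points to a structure of the samples beside genotype.

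The count of separated 2-fold probe sets was 166. It was 99 at or above the median brightness, by fewer probe sets, 704 at 1.5-fold, and 160 to 409 with an array left out. Syde1 stayed between 0.095 and 0.145 and was not called under any alternative run. Rnase2a, Ang2, Alb and Spink1 stayed higher under all 14 alternatives each and lost their call without any 1 array, and the last 3 also with the block. Their measured differences stayed at 8.52 to 8.86, 5.93 to 6.56, 3.42 to 3.66 and 3.55 to 3.94, the first pair against wild-type readings below the first quartile, while 1 residual degree of freedom was left of 2, so the calls ended with little change in the differences.

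The count of called lists was 8. It was 14 with the replicate block, which added spongiotrophoblast (0.049), uterine natural killer (0.0042), cathepsin (0.034), integrin (0.043), cell cycle (0.043) and mitochondrial genes (0.049), 0 with an estimated correlation, 0 with fry, 14 at an adjusted p under 0.1, and 8 to 14 with an array left out. Directions of some lists turned when an array was left out, with a call before or after the turn. Adjusted p then ranged from 1.2e-09 to 0.830 for uterine natural killer and 5.0e-10 to 0.228 for interferon response genes. It ranged from 0.00041 to 0.830 for decidual stroma and 4.7e-05 to 0.690 for pregnancy-specific glycoprotein genes. It ranged from 1.9e-14 to 0.403 for cell cycle and 0.034 to 0.432 for ribosomal protein genes. Uterine natural killer, decidual stroma and cell cycle genes were called in both directions, depending on the array left out. Interferon response, pregnancy-specific glycoprotein and ribosomal protein genes were called lower only. The turn to higher was not called for interferon response (0.228) or pregnancy-specific glycoprotein genes (0.690). The cause of the turns was not tested. Among other values of lists, 369 kept their side, 28 gained and 27 lost a call. Among those of named genes, 1211 kept it, 24 gained and 19 lost a call, and 0 turned. Turns of sign with no call on either side, 41 for lists and 8 for genes, are counted as kept. At or above the median brightness 2 lists, Y-linked and lymphocyte genes, had fewer than 5 members and were not tested.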

Other observations

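The tests in this part were chosen after the results were seen, and so were the genes it names. Of the probe sets with no gene listed, 1426438_at, 1426439_at and 1452077_at followed the Y-linked genes. The brightest in wild type, 1426438_at, read 9.45 and 9.76 in the wild-type arrays, 1.78 in the first knockout-labelled array and 7.67 in the second. Others did not follow them, such as 1458629_at, which was higher by 2.31.

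Changed genes, here separated by at least 1.5-fold, concentrated in 1 window of 5 Mb around a cluster of ribonuclease genes, on another chromosome than Syde1. It held 12 changed genes of 73 (7 higher, 5 lower), against 235 of 18135 over all windows and 4 in the next. Chance positions are not excluded: the one-sided permutation p was 0.0001, the smallest that 10000 permutations can give, but it treats neighbouring genes of a family as independent. Without the ribonuclease family the window held 6 changed genes of 64, against 4 in the next (one-sided permutation p = 0.112). Strain sequence carried along with Syde1 is argued against for this window, because the window lies on another chromosome. Of the 211 genes flanking Syde1, 1.42% changed, near the 1.30% of all genes. The 16.4% in the window is no standard for that share, since the window was picked for its high count. Of the 12, 6 are ribonuclease or angiogenin genes, and whether their probes cross-hybridize between paralogs was not tested. Ang lay at -0.91, Rpgrip1 at -0.93, Ppp1r3e at -0.95 and Ccnb1ip1 at 0.88. A strain difference in this segment, for which the labels give no strain, is an untested hypothesis.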
